A study of Homo sapiens with 7 samples.

How the data were processed

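Chromatin accessibility was measured by ATAC-seq, in which a transposase inserts sequencing adapters into open chromatin, in Kasumi-1 cells. Kasumi-1 is an established acute myeloid leukaemia line that carries the RUNX1-RUNX1T1 fusion gene. Per the labels, 4 libraries came from cells given a scrambled control shRNA and 3 from cells with lentiviral silencing of PHF19, a Polycomb-like protein that binds Polycomb repressive complex 2 (PRC2). Puromycin at 2 µg/ml was added 48 hours after the shRNA and kept for at least 24 hours, and each library started from 10000 cells. Nothing in the labels says whether libraries of a group came from separate cultures, so the authors' p-values measure only the spread between these libraries, which may be technical.

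The deposited values are a pair of lists of regions, those increased and those decreased in the knockdown. Per the file headers, each region has the log2 of the authors' mean normalised read count over all libraries and over each group, a log2 fold change, a p-value and a false discovery rate (FDR), all computed by the authors before deposit. The deposited annotation gives the genomic feature, the nearest gene and the distance in base pairs to its transcription start site (TSS), per the file headers. Bowtie2 2.4.1, Picard 2.2.4, deepTools 1.5.12 and MACS2 2.2.6 are named per the submitters' processing notes, which give no role, order or setting for them. The tool behind the fold changes, the normalisation, any shift of reads for the transposase and the way regions were merged across libraries are not given in the sources used here. The deposited log2 fold was closer to 0 than the difference of the 2 group means in every region, as a shrunken estimate is, and the log2 group means were floored at 0. The lists hold the authors' means and no value per library, so no SD, n or depth per library is attached to a region, and no replicate was left out.

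Group columns were assigned from their content. The overall mean equalled the group means weighted by 3 and 4 libraries, with a median weight of 0.429 for the knockdown column, and 98.5% of regions lay within 0.001 of that weight. The knockdown column was the higher in every region of the increased list and the lower in every region of the decreased list. Multiplying the FDR by the rank of the p-value and dividing by the p-value gave 52675 tested regions. At the largest listed FDR this implies 8925 passing regions, 110 more than listed, and these 110 and the other tested regions were not analysed here. No listed FDR lay above 0.05, and the smallest absolute log2 fold was 0.59 among increased regions, or 1.50-fold, and 0.62 among decreased regions.

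The submitters' processing notes name build hg38, but the deposited coordinates are not those of that build. Gene starts equalled those of GRCh38 for only 0.137% of the matched regions, and on 13 chromosomes a region lay beyond the end of the last GRCh38 gene. Coordinates are therefore given as deposited, 1-based, and read as hg19. A RefSeq gene table of GRCh38.p14 was used only for gene names, gene types and the number of protein-coding genes per chromosome. Gene identifiers of 8789 regions (99.7%) matched it.

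Tests used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. The share of increased regions and of each feature class has an exact Clopper-Pearson 95% interval, which covers counting error only, since neighbouring regions are not independent. Feature classes and chromosomes were compared between increased and decreased regions with 2-sided Fisher exact tests, and regions per chromosome with the number of protein-coding genes by exact binomial tests. Medians were compared with 2-sided permutation tests of 100000 resamples. Genes of 25 lists fixed before the data were examined were each compared with 10000 random lists of as many protein-coding genes, by 2-sided permutation p over 50 tests. Tests of feature classes, chromosomes, gene lists, gene families and relations across chromosomes were each adjusted by Benjamini-Hochberg with a threshold of 0.05. Comparisons of medians, of immediate early genes with gene families and of the parts of chromosome 6 were not adjusted. Nor were the tests of explanations. A count of genes adjusted over the list alone was not made, since only regions past the authors' threshold carry a p-value here. A list counts a gene where at least 1 listed region has it as the nearest gene, and a promoter is within 3 kb of a TSS. All protein-coding genes served as the background, including genes with no accessible region. In all, 7 list symbols without a protein-coding match were left out, and 20 lists share members with another. Random placements of the regions, uniform along each chromosome, ignore where open chromatin lies and so do not test clustering of the change, and their values are not printed. Tested on simulated data, lists of 45 genes were called in 95% of 20 draws at 2 times and in 95% at 0.3 times the rate of all genes, and in 0% at an equal rate. The simulated lists were adjusted together and most were altered, so these shares can overstate the power for the 25 lists. Simulated regions fell on genes evenly, so false calls from gene length or the space around a TSS were not simulated. With labels of the regions permuted 50 times, any feature class was called in 4% and any chromosome in 0% of draws.

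The rule for named genes, fixed before the data were examined, took per list the genes of the 10 largest absolute folds and of the 5 largest promoter folds, and the 5 genes with the most regions. It also took up to 4 members of each gene list with the largest absolute fold, and PHF19, EZH2, SUZ12, EED, RUNX1, RUNX1T1, KIT, CEBPA, SPI1 and CDKN1A. Loci without a gene name or without a protein-coding gene were passed over, 5 among the largest increased and 2 among the largest decreased regions. Not every gene this rule takes is printed, and some are not reported here. Other genes named in the text were chosen after their values were seen.

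Alternatives were a stricter fold or FDR, merging regions within 1 kb, autosomes only, promoter or distal regions only, narrower promoters and narrower gene assignment. No genome sequence of the build was used here, so motif, G+C and CpG content, chromosome length, and feature classes or distances from a reference annotation were left out. For the same reason random lists were not matched on the space around a TSS or on gene length, as the plan had set, and the planned unmatched lists gave the values printed. Tests on values per library were left out because the lists hold group means only.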

Results

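The data were 8815 regions of accessible chromatin listed as changed between Kasumi-1 cells with PHF19 knockdown (3 libraries) and cells with a scrambled control (4 libraries). The comparison asks how reduced PHF19, an accessory subunit of the histone H3 lysine 27 methyltransferase PRC2, alters chromatin accessibility in this leukaemia line. Folds, mean normalised read counts and FDR of single regions are the authors' own, from the authors' deposited tables, and carry no SD or n. A fold is knockdown over control, and coordinates are as deposited, read as hg19. The read depth of each library is unknown here.

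Accessibility, as normalised by the authors, was higher in the knockdown at 8615 regions and lower at 200. How it was normalised is not given, and the balance of increased and decreased regions can depend on that. Increased regions were 97.7% of those listed (95% Clopper-Pearson interval 97.4 to 98.0%), 16.4% of the 52675 regions tested, and decreased regions were 0.380% of those tested. The promoter of CYB5A, which encodes the electron carrier cytochrome b5, had the largest increase among named genes, with a log2 fold of 2.25 and authors' means of 43.4 reads in the knockdown and 6.33 in the control (chromosome 18, 71959146 to 71959546). It was followed in the authors' deposited table by a region 15.5 kb upstream of AACS, which encodes acetoacetyl-CoA synthetase (2.21), and by the promoter of EEF1A1, the translation elongation factor that delivers aminoacyl-tRNA (2.11). The promoters of ACTB, which encodes beta-actin (1.88), and SPCS3, a subunit of the signal peptidase (1.82), were among the 5 largest promoter increases at named protein-coding genes. An intronic region of NBPF14 also lay among the largest increases (2.16), but this gene belongs to a family of near-identical copies, so its reads are of uncertain origin.

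The largest decrease at a named gene was 8.12 kb upstream of ZNF157, a zinc finger gene, where the log2 fold was −1.75 with authors' means of 4.23 reads in the knockdown and 25.7 in the control (chromosome X, 47221133 to 47221878). The promoters of KCNN3, a calcium-activated potassium channel (−1.35), and BCL6B, a transcriptional repressor (−1.30), fell in the authors' deposited table. So did a distal region near TFAP4, a basic helix-loop-helix transcription factor (−1.34), and an intron of PRDM11 (−1.45), which also had 2 increased regions. RNF213, STAC2, SERPINB9, TXNDC5 and ACOT11 each had 2 decreased regions, RNF213 also had 1 increased region, and SERPINB9 encodes an inhibitor of granzyme B.

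The median log2 fold was 0.97 among increased regions (interquartile range 0.84 to 1.12) and −0.96 among decreased regions (−1.04 to −0.89). Median absolute folds differed by 0.0034, and a permutation test did not separate them (p = 0.839). The planned splits gave differences in opposite directions, −0.075 at promoters (permutation p = 0.0241) and 0.060 at distal regions (permutation p = 0.00321). Decreased regions rested on fewer reads. The authors' mean over all libraries had a median of 7.05 reads there and 18.3 reads in increased regions (permutation p = 2e-05), and it was under 10 reads in 66.5% and 26.9% of regions. An FDR of at most 0.01 was reached by 3951 increased (45.9%) and 27 decreased regions (13.5%). No listed absolute log2 fold was under 0.59, so the folds describe selected regions, and their comparison turned direction when the difference of the unshrunken group means was used (−0.71, permutation p = 1e-05, the smallest the resamples can give), an alternative chosen after seeing the data. The knockdown mean lay at the floor in 49 of the 200 decreased regions, and the control mean in 88 of the 8615 increased ones.

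Increased regions lay at promoters more often than decreased ones. Promoters held 4318 increased regions (50.1%) and 58 decreased regions (29.0%), an odds ratio of 2.46 (Fisher exact test, adjusted p = 1.64e-08). The tests of features and distances treat regions as independent draws, which neighbouring regions are not. What share of all tested regions lay at promoters was unknown here. Introns held 20.5% of increased and 32.0% of decreased regions (odds ratio 0.548, exact adjusted p = 0.000563), exons 1.86% and 6% (adjusted p = 0.00106) and untranslated regions 0.743% and 2.5% (adjusted p = 0.0299). Intergenic shares of 26.8% and 30% did not pass the test (exact adjusted p = 0.333), nor did the 2 and 1 regions just downstream of genes (adjusted p = 0.0798). The median distance to a TSS was 2.90 kb for increased and 10.9 kb for decreased regions (permutation p = 0.0150). Regions within 1, 3, 10 and 100 kb of a TSS made up 46.9%, 50.1%, 56.8% and 83.8% of increased regions, and 20.5%, 29%, 47% and 91.5% of decreased regions. Among regions with an absolute log2 fold of at least 1 the promoter odds ratio was 1.20 (exact adjusted p = 0.645), and the median distance was 8746 bp greater in increased regions (permutation p = 0.309), so neither difference held there. The intron (odds ratio 0.853), exon (0.727) and untranslated region (0.176) calls ended there too (exact adjusted p = 0.645, 0.659 and 0.0620).

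**Figure D1:**
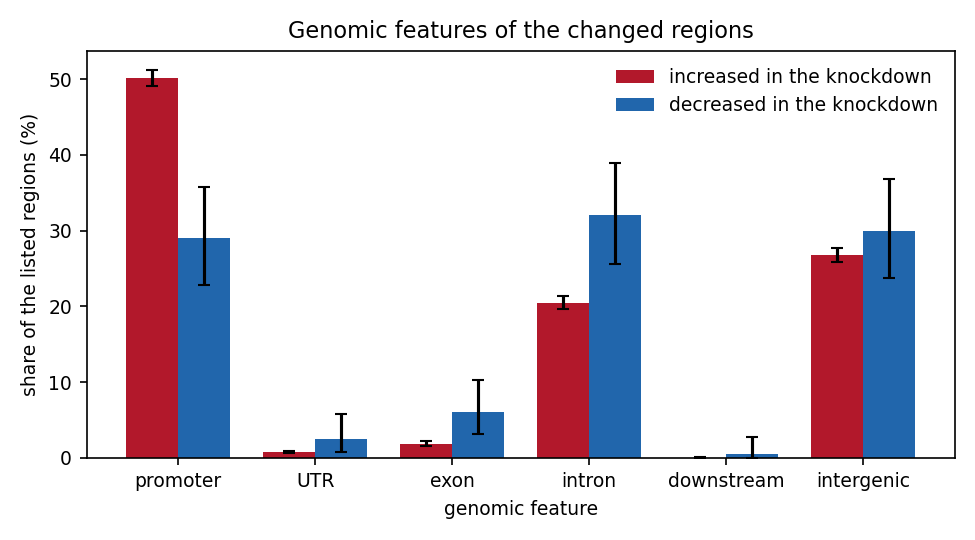
Share of the 8615 increased and 200 decreased regions in each genomic feature class, in percent, with exact 95% Clopper-Pearson intervals as error bars. Promoters held 50.1% of increased and 29.0% of decreased regions, and introns 20.5% and 32.0%.

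Immediate early genes, the transcription factors and phosphatases induced within minutes of a stimulus, had increased regions at the highest share of members among the 25 lists when all listed regions were used. Of 33 genes, 21 (63.6%) had an increased region and 20 had one at the promoter, against 25.2% and 17.5% of all protein-coding genes (adjusted permutation p = 0.0025 for both). Examples from the authors' deposited table are IER2 (log2 fold 1.28), the MAP kinase phosphatases DUSP1 (1.26) and DUSP5 (1.23), and FOS (1.20), a subunit of the AP-1 transcription factor. With an absolute log2 fold of at least 1 this call ended (adjusted permutation p = 0.0550), while the ratio to all genes was 2.94, against 2.52 with all regions, and neuronal genes had the higher ratio there (4.14).

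Genes of haematopoietic stem and progenitor cells gained regions at 22 of 46 members (47.8%, adjusted permutation p = 0.0150). They included the lymphoid and progenitor transcription factor IKZF1 (largest log2 fold 1.78, intronic), RUNX1 (1.63), the checkpoint receptor HAVCR2 (1.39) and CD38 (1.31), an ectoenzyme used as a differentiation marker. IKZF1 lies on chromosome 7, without which the list was still called (adjusted permutation p = 0.0140, chosen after seeing the data). The RUNX1 region was intronic, 52.1 kb from a TSS, and RUNX1 promoter regions had log2 folds of 1.11 and 0.98. The control mean of the HAVCR2 region lay at the floor, 1 read. RUNX3 was the member with a decreased region. Only 12 members had an increased promoter, which did not pass (adjusted permutation p = 0.655), and regions within 10 kb of a TSS did not pass either (adjusted permutation p = 0.361). As for every list, the random lists were not matched on gene length. At an absolute log2 fold of at least 1 the call ended as well (adjusted permutation p = 0.0800), with a ratio to all genes of 2.30, against 1.89 with all regions.

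Synapse and ion channel genes of neurons had an increased region at 36 of 66 members (54.5%, adjusted permutation p = 0.0025), of which 24 had distal regions only. Examples were the glutamate receptor genes GRM7 (log2 fold 1.97) and GRIK2 (1.70), the axon guidance receptor ROBO1 (1.70) and CSMD3 (1.71). The GRM7 region was intronic, with a control mean of 1.16 reads. The regions of GRIK2, ROBO1 and CSMD3 were intergenic, 1018, 599 and 540 kb from the TSS. The list was not set apart at promoters (12 members, adjusted permutation p = 1) or with regions within 100 kb of a TSS (adjusted permutation p = 0.109), and the random lists were not matched on gene length. It was the list still called at an absolute log2 fold of at least 1 (ratio to all genes 4.14, adjusted permutation p = 0.01). Ribosomal protein genes, a control list, had an increased region at 35 of 73 members (47.9%, adjusted permutation p = 0.0025), 34 of them at the promoter, with RPL15 (1.81) and RPL30 (1.40) the largest. This call ended at an absolute log2 fold of at least 1 (adjusted permutation p = 1).

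HOX genes, which set body-axis identity and are textbook PRC2 targets, had an increased region at 2 of 39 members (5.13%), fewer than random lists (adjusted permutation p = 0.0150). These were HOXA5 at its promoter (log2 fold 0.93) and HOXD11 at a distal region (0.93). The ratio to all genes was 0.203. The random lists were not matched on the space around a TSS, which bears on how many regions a gene can be nearest to. The call was absent for promoters (ratio 0.146, adjusted permutation p = 0.0850), without chromosome 7 (ratio 0.149, adjusted permutation p = 0.0643, chosen after seeing the data), within 10 kb of a TSS (ratio 0.269, adjusted permutation p = 0.190) and at an absolute log2 fold of at least 1 (0 genes, adjusted permutation p = 0.142). Developmental transcription factors typical of PRC2 domains had an increased region at 34 of 129 members (26.4%, adjusted permutation p = 1), but at the promoter of only 5 (3.88%, adjusted permutation p = 0.0025). EOMES (1.83), NR2F2 (1.68), PRDM13 (1.55) and TWIST1 (1.42) had the largest folds, none of them at a promoter. Keratin and epithelial genes, the other control list, had 0 of 55 (adjusted permutation p = 0.0025), a call that ended at an absolute log2 fold of at least 1 (adjusted permutation p = 0.0633). T and NK lymphocyte markers had 7 of 45 with any region (adjusted permutation p = 0.626) and 1 at a promoter, fewer than random lists (adjusted permutation p = 0.0320).

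The other lists passed neither test. PRC2 subunits had increased regions at 6 of 15 genes (EED, EZH2, LCORL, PHF19, RBBP4 and RBBP7), each with a promoter region (adjusted permutation p = 0.878 for any region and 0.338 for promoters). PRC1 subunits had 10 of 25, 9 at the promoter (adjusted permutation p = 0.626 and 0.257). The largest folds were at RYBP (log2 fold 1.32, 172 kb from its TSS) and SCML2 (1.12, at its promoter). Granulocyte and myeloid differentiation genes had 7 of 50, among them NCF1 (1.17), whose reads may be shared with near-identical pseudogenes, and the receptor gene CSF1R (0.89). Monocyte, macrophage and dendritic markers had 8 of 42, including CD14 (1.26). Erythroid markers had 5 of 31, megakaryocyte and platelet markers 5 of 22, B lymphocyte markers 7 of 35, and mast cell, basophil and eosinophil markers 3 of 22. RUNX1-RUNX1T1 partners and targets had 12 of 37, including CXCR4 (1.29, 264 kb from its TSS) and BCL2 (1.22, intronic). Inflammatory and NF-kappaB genes had 15 of 33 (adjusted permutation p = 0.124), interferon response genes 12 of 42, Wnt and Notch genes 16 of 63, and adhesion and migration genes 14 of 36. Cell-cycle inhibitors had 11 of 29, including E2F7 (1.24) and BTG1 (1.10), cell-cycle drivers 10 of 42, including CDC25C (1.29), and apoptosis genes 13 of 35, including MCL1 (1.25) and PMAIP1 (1.07).

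**Figure D2:**
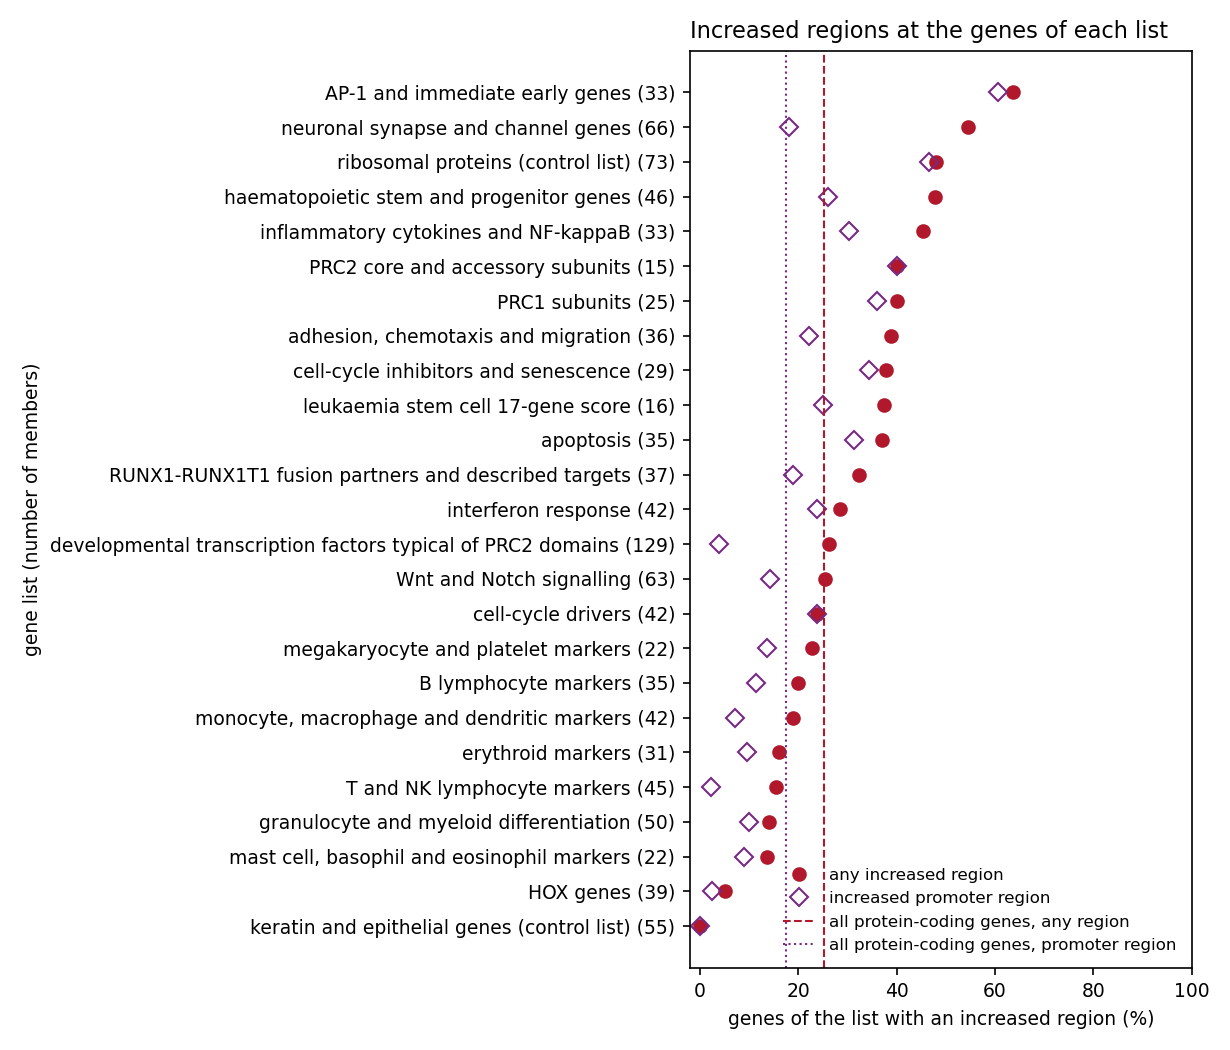
Percent of the genes of each of 25 lists with any increased region (filled circles) and with an increased promoter region (open diamonds), with the number of members in brackets. Vertical lines mark all protein-coding genes, at 25.2% for any region and 17.5% for promoters, and AP-1 and immediate early genes lie highest at 63.6% and 60.6%.

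No list was set apart among decreased regions by the permutation test, where 1 of the 25 had an unadjusted p under 0.05. That list was the 17-gene leukaemia stem cell score, with decreased regions at ARHGAP22 (log2 fold −1.01) and SMIM24 and increased regions at 6 of 16 members, among them MMRN1 (1.43) and the cyclin-dependent kinase CDK6 (1.13). Set directly against each other, increased and decreased genes passed the threshold in no list (smallest unadjusted Fisher exact p = 0.0242, for the same score, adjusted p = 0.605). With 164 decreased genes this test could hardly detect fewer members among them, since 36 neuronal genes with increased regions and 0 with decreased ones gave an exact p of 0.629.

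Of the genes fixed in advance, PHF19 itself had 3 increased regions, at its promoter (log2 folds 1.10 and 0.72) and 15.4 kb upstream (1.10). These values describe chromatin and give no check of the knockdown, since no transcript or protein level was analysed here. EZH2, the PRC2 methyltransferase, had 3 increased regions, the largest at its promoter (1.05). It lies on chromosome 7, where 37.5% of protein-coding genes had an increased promoter, against 17.5% of all protein-coding genes. EED, the subunit that reads trimethylated H3 lysine 27, had 1 increased region, at its promoter (1.40, FDR 1.95e-06). RUNX1 had 5 increased regions (0.92 to 1.63), RUNX1T1 3 (0.91 to 1.03), and KIT, the stem cell factor receptor, 2 (0.84 and 0.74). SUZ12, CEBPA, SPI1 and CDKN1A had no listed region, which does not show that they did not change.

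Increased regions were spread unevenly over chromosomes. Chromosome 7 held 1042 increased and 3 decreased regions. The increased ones were 111 per 100 protein-coding genes, 2.58 times the number its genes would give (exact binomial adjusted p = 4.62e-163). Among the genes named above, ACTB, CDK6, EZH2, HOXA5, IKZF1, NCF1 and TWIST1 lie on chromosome 7. The binomial and Fisher tests of chromosomes treat regions as independent draws, which neighbouring regions are not. How many tested regions lay on each chromosome was unknown here. Chromosomes 5 (85.3 per 100 genes), 3 (81.7), 4 (75.1) and 21 (72.8) were also high, and chromosomes 22 (10.9), 16 (12.6) and 17 (12.8) were low. Chromosome 17 held 35 of the 200 decreased regions and 150 increased ones (odds ratio 0.0835, Fisher exact adjusted p = 1.27e-21), and chromosome 20 held 15 and 80 (adjusted p = 3.31e-08). In all, 14 of 23 chromosomes differed between increased and decreased regions, 7 with an absolute log2 fold of at least 1. Across the 23 chromosomes, increased and decreased regions per 100 genes were inversely related (Pearson r = −0.61, adjusted permutation p = 0.00774, Spearman rho = −0.751, adjusted p = 1.2e-04, 3 relations computed, all chosen after seeing the data). Pearson r was −0.606 without chromosomes 5 and 7.

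**Figure D3:**
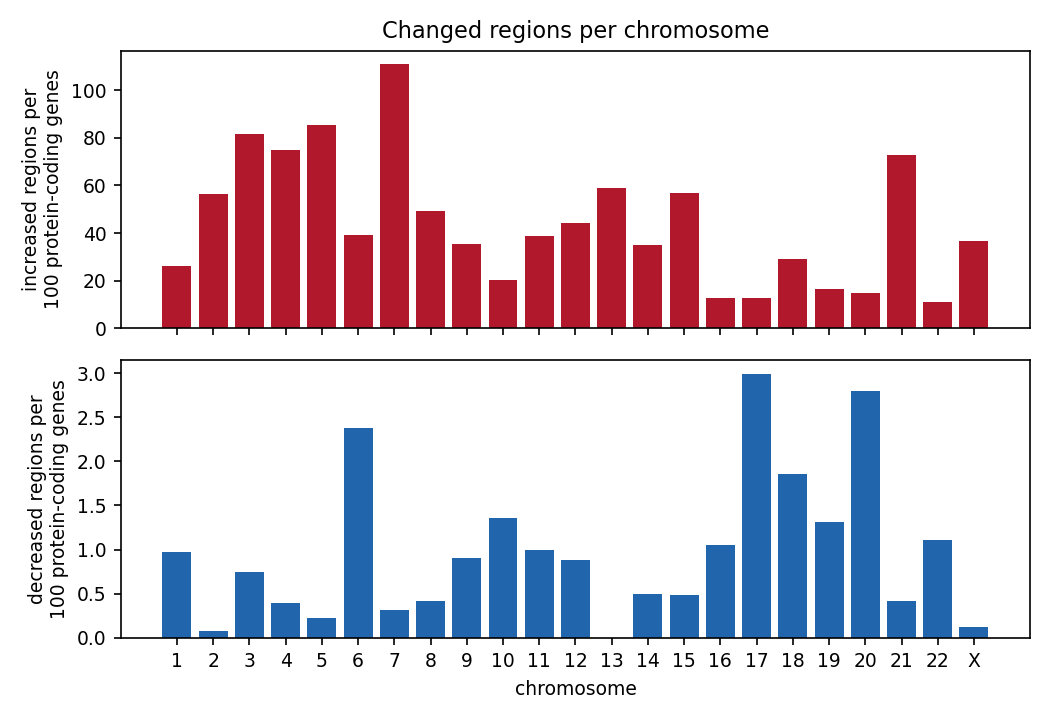
Increased (upper) and decreased (lower) regions per 100 protein-coding genes on each chromosome, on separate vertical scales that start at 0. Chromosome 7 stands highest for increased regions at 111, and chromosome 17 highest for decreased regions at 2.99.

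Increased regions were assigned to 5062 protein-coding genes and decreased ones to 164, with 26 genes in both, where 41.4 would be shared by independent lists among 20056 genes. Of all genes, 609 had at least 3 increased regions, and none had 3 decreased ones. INSIG1, an endoplasmic reticulum protein of the sterol response, ETV1, an ETS transcription factor, HS3ST1, a heparan sulfate sulfotransferase, MAT2B, a subunit of methionine adenosyltransferase, and AKAP13 each had 10. INSIG1 and ETV1 lie on chromosome 7, which held the most increased regions per gene. INSIG1 had its largest fold at the promoter (log2 fold 1.73, FDR 1.39e-06), whereas the largest HS3ST1 region lay 698 kb from its TSS (2.09). Another increased region lay within 50 kb for 46.7% of increased regions, and another decreased region for 10.5% of decreased regions, shares that depend on the number of regions and on where open chromatin lies.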

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

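The alternative without chromosome 7 and the one with the difference of group means were chosen after seeing the data. No paired analysis was possible because the deposited lists hold group means and no value per library, which also ruled out leaving out a replicate or regrouping the libraries. Motif, sequence content, chromosome length, matched random lists and reference annotation alternatives were not run, for want of a genome of the build used here. With an absolute log2 fold of at least 1, 3737 increased and 73 decreased regions were left (98.1% increased). There the promoter odds ratio was 1.20 (exact adjusted p = 0.645), and the distance difference turned to 8746 bp (permutation p = 0.309). The intergenic odds ratio turned to 1.24, and 7 chromosomes differed between increased and decreased regions. Against gene number, 1 chromosome stood apart for decreased regions, and 1 list (neuronal genes) had more increased regions and 0 fewer. Fewer regions entered these tests. With an FDR of at most 0.01, 3951 and 27 regions were left (99.3% increased). The difference in absolute log2 fold was −0.075 at promoters (permutation p = 0.0241), 0.060 at distal regions (p = 0.00321) and −0.71 with the difference of group means (p = 1e-05, the smallest possible); the cause was not tested. Regions within 10 kb and promoter regions each gave 2 lists with more increased regions, and without chromosome 7 there was 1 with fewer. Genes with 5 or more increased regions numbered 125. Merging regions within 1 kb left the promoter call in place (odds ratio 2.24), as did a 1 kb promoter (3.42), and autosomes only gave 8303 and 199 regions. The ratio to all genes of some lists crossed 1. That of developmental transcription factors went from 1.04 to 0.787 within 100 kb of a TSS, 0.284 within 10 kb and 0.221 at promoters, of which the last 2 passed the test. Cell-cycle drivers went from 0.943 to 1.05 at an absolute log2 fold of at least 1, 1.01 within 100 kb, 1.25 within 10 kb and 1.36 at promoters. Wnt and Notch genes went from 1.01 to 0.980, 0.940, 0.749 and 0.815 under these settings in turn, and to 0.991 without chromosome 7. At an absolute log2 fold of at least 1, monocyte markers went from 0.755 to 1.26 and megakaryocyte markers from 0.900 to 1.20. None of these lists but the first passed a test, and why the ratios crossed 1 was not tested. Of the other comparisons of single classes or lists, 102 kept their direction and side of the threshold, 16 lost and 2 gained a call. The authors' means were under 10 reads in 66.5% of decreased regions.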

Other observations

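The tests of gene families, of immediate early genes against these families, of chromosome 6, of relations across chromosomes, and of each explanation were chosen after the data were seen, except the test of broadly expressed families, whose prediction was written first, when the share of ribosomal protein genes had been seen. Of 10 families with basic cellular roles, 5 had an increased promoter more often than random lists. They included 15 of 34 aminoacyl-tRNA synthetases (44.1%, adjusted permutation p = 0.00128), 25 of 65 chaperones (38.5%, adjusted p = 8e-04), 21 of 56 translation initiation factors (37.5%, adjusted p = 0.00274) and 13 of 36 ubiquitin-conjugating enzymes (36.1%, adjusted p = 0.0232). Mitochondrial ribosomal proteins were the other, with 22 of 77 (28.6%, adjusted permutation p = 0.0359). Complex I subunits (32.4%), spliceosome proteins (33.3%, adjusted permutation p = 0.0622 for both), proteasome subunits (22%, p = 0.559) and ATP synthase and cytochrome oxidase subunits (16.7%, p = 1) did not pass. Core histones had 2 of 76 (adjusted permutation p = 8e-04), olfactory receptors 6 of 392, protocadherins 1 of 66 (adjusted p = 8e-04 for both) and defensins 0 of 45 (adjusted p = 0.00213). Bitter taste receptors had 1 of 25 (adjusted permutation p = 0.132), solute carriers 54 of 386 (adjusted p = 0.0939) and ZNF zinc finger genes 88 of 517 (adjusted p = 0.869), none of which passed. Immediate early genes, at 60.6%, exceeded the 27.3% of the broadly expressed families (odds ratio 4.09, Fisher exact p = 1.23e-04). These families include core histones and leave out ribosomal proteins, at 46.6%, against which immediate early genes were not tested.

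On chromosome 6, the first 50 Mb held 47 increased and 19 decreased regions, and the rest 364 and 6 (odds ratio 0.0408, Fisher exact p = 1.98e-12). The boundary was chosen after the data were seen and the test treats neighbouring regions as independent, so the p-value only describes this split. SERPINB9 and TXNDC5, with 2 decreased regions each, lie in that first part. For gene density, the number of protein-coding genes was divided by the end of the last listed region, a stand-in for chromosome length. Gene density was inversely related to the percent of genes with an increased promoter by rank across the 23 chromosomes (Spearman rho = −0.533, adjusted permutation p = 0.0098) but not by Pearson r (−0.384, adjusted p = 0.0700). Decreased regions per 100 genes rose with gene density by rank (Spearman rho = 0.607, adjusted permutation p = 0.00379) but not by Pearson r (0.407, adjusted p = 0.0700).

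Of the listed regions, 97.7% were increased. Of 168 HOX and developmental transcription factor genes, 6 (3.57%) had an increased promoter, against 17.5% of all genes (permutation p = 2e-04, the smallest possible). The increase was thus not concentrated at promoters of these textbook PRC2 targets, as the counts of both lists had already shown. Olfactory receptors (6 of 392) and keratin genes (0 of 55) were also low, so the test does not single out PRC2 targets. No H3 lysine 27 methylation was analysed here, so opening of PRC2 target promoters in these cells stays open. A larger share of reads in open regions of the knockdown libraries may contribute, since promoters of broadly expressed families were increased at 27.3%, against 17.3% of other genes (Fisher exact p = 2.46e-08), although any general gain at open promoters would give this. Among broadly expressed and ribosomal protein genes the share differed between chromosomes (permutation p = 1e-04, the smallest possible, also without chromosome 7 or without histones). It ran from 9.09% on chromosome 22 (1 of 11 genes) to 60% on chromosome 21 (6 of 10), with 45.8% on chromosome 7 (11 of 24). Unequal power between chromosomes could give this, so one scaling factor for all regions stays open. An effect of PHF19 loss and differences in library quality stay open, and values per library would be needed to separate them.

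Chromosome 7 held the most increased regions. Chromosome 7 lay 19.9 percentage points above the line of promoter share on gene density through the other chromosomes, whose largest residual was 12.8. As chromosome 7 was chosen for its count and left out of the fit, this comparison cannot decide on a trend with gene density. Chromosomes 14 and 15 lay close to chromosome 7 in density (5.74 and 6.03 genes per Mb, against 5.91). Increased promoters were found at 17.5% and 22.7% of their genes, against 37.5% on chromosome 7, so density alone did not set the share. More reads on chromosome 7 in all libraries, and hence more power, would give higher control means and smaller folds there. Its increased promoters had lower control means than those of other chromosomes (medians of 20.4 and 23.1 reads, permutation p = 0.00355). Their log2 fold was larger (by 0.13, permutation p = 1e-05, the smallest possible), but listed regions with fewer reads need a larger fold to pass. Which promoters are listed depends on their folds and reads together, so neither comparison can decide on this explanation. Regions not listed were not analysed. A gain of chromosome 7 in the knockdown cells stays open. On it, 16 of 16 bins of 10 Mb (100%) held more increased regions than the median bin of the other chromosomes. So did 19 of 20 bins on chromosome 3 (95%), and no copy number was measured. Among broadly expressed and ribosomal protein genes chromosome 7 had an increased promoter at 11 of 24 (45.8%). Chromosomes 21 (6 of 10, 60%), 3 (18 of 31, 58.1%), 5 (14 of 27, 51.9%) and 2 (20 of 41, 48.8%) lay above it. Without core histones the X rose from 35.7% to 62.5% (5 of 8) and also lay above chromosome 7 (10 of 22, 45.5%). These shares rest on few genes, and an effect of PHF19 was not tested.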
